A study of Mus musculus with 6 samples.

How the data were processed

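The table holds 1 intensity per probe set and array on a linear scale, as deposited by the authors, and the medians of the 6 arrays lay close together; background correction, normalization and probe set summary are not given in the sources used here. Per the labels' protocols, total RNA was isolated with a Qiagen kit and biotinylated cRNA was made by the standard Affymetrix protocol from 6 ug of total RNA. How the CD4+ T cells were isolated, and with what purity, is not given in the sources used here. The scale was read from the values, which are positive and not whole numbers, and whether and how the arrays were centred remains unknown. Median intensity was 166, 166 and 161 in WT 1 to 3 and 161, 171 and 149 in CBS-KO 1 to 3, which is 7.51, 7.51, 7.47, 7.47, 7.55 and 7.37 as log2(intensity + 16). The CBS-KO median was -0.03 relative to WT, within the limit of 0.5 set beforehand, so no shift was applied. Directions are CBS-KO minus WT throughout.

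Values were log2(intensity + 16), and a probe set was tested if its mean over the 6 arrays lay above the 40th percentile, which kept 20856 of 34760. Of all probe sets, 21640 named 1 gene, 1321 several and 11799 none, and 13862 of the tested ones named 1 gene (12776 genes). The gene table's 21553 matched Entrez identifiers changed 0 symbols. Of all probe sets, 6260 (18%) had the same value on at least 2 arrays, 5 of them 1 value on all arrays, and 8 of the called probe sets had such ties. Among 670 genes with several tested probe sets, 0 had probe sets called in opposite directions. The rule that leaves out control probe sets by the AFFX prefix removed none, because no name on this array carries it.

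A linear model (limma 3.58.1 in R 4.3.3, eBayes with a trend) compared the groups, two-sided, and p was adjusted by Benjamini and Hochberg over all tested probe sets, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, each gene represented by its brightest tested probe set that names 1 gene, with camera at an estimated correlation and fry beside it. Of 38 lists, 36 had at least 5 measured genes and were tested; the liver and sex-linked lists had fewer, and the sex-linked genes are given by array. The comparison, the model, the filter, the offset, the list members, all alternatives but those listed below as added later, and the rule for named genes were chosen before the data were examined. That rule names the 12 largest increases and decreases among called probe sets that name 1 gene and whose groups do not overlap, a fixed set of genes, and up to 4 list members of smallest p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

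Alternatives were quantile normalization, a common array median, no filter or one at the 60th percentile, offsets of 1 and 64, other variance models, array weights, a plain t-test, the replicate number as a block, 1 probe set per gene, the mean of a gene's probe sets, a 1.5-fold threshold, and each array left out in turn. Added after the data were seen were the restriction to probe sets that name 1 gene, sex as a model term, and the female arrays alone; in the last 2 the estimate rests on CBS-KO 3. The gene order of GRCm38.p6 was used for names and neighbours only. On simulated values with the same layout of 20856 probe sets, 58% of 100 changes of 1 log2 unit and 86% of 100 changes of 2 were recovered, with 5 unchanged probe sets called and 0 in the wrong direction. Of 20 simulated lists of 20 genes shifted by 0.5, 20 were called, and 0 of 20 unshifted ones. The simulated probe sets varied independently and alike in both groups. In the data the CBS-KO arrays varied more, and estimated correlations within the lists reached 0.972. These simulations therefore do not show how often lists whose genes move together are called without a shift. With 3 arrays per group, the number of arrays limits precision.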

Results

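Gene expression was measured on Affymetrix arrays in CD4+ T cells, the helper and regulatory class of T lymphocytes, from C57BL/6 mice of 6 weeks of age. Cells of wild-type (WT) mice were compared with cells of mice lacking CBS (CBS-KO), cystathionine beta-synthase, the enzyme that joins homocysteine and serine to cystathionine and that also produces hydrogen sulfide. Each group held 3 arrays, which the labels call biological replicates, and this number limits the precision of every value. Each array gave an intensity for 34760 probe sets, and the array medians lay between 7.37 and 7.55 on the log2 scale. Across probe sets, which are not independent replicates, Pearson's r was 0.989 to 0.994 between WT arrays, 0.970 to 0.989 between CBS-KO arrays and 0.949 to 0.978 between arrays of different groups. The median SD of a tested probe set was 0.112 log2 units among WT arrays and 0.214 among CBS-KO arrays.

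The targeted gene itself did not separate the groups. The probe set of Cbs had a log2 intensity of 7.35 ± 0.15 (SD, n = 3) in WT and 7.41 ± 0.20 (SD, n = 3) in CBS-KO cells, a difference of 0.06 (95% confidence interval -0.27 to 0.39, limma adjusted p = 0.801). The two-sided exact permutation test of the means gave p = 0.7, where 0.1 is the smallest p that 3 against 3 arrays allow. Its mean level lay at the 47.9th percentile of all probe sets, and which part of the gene the probe set covers is not given in the sources used here, so it does not check the labels. Of the genes near Cbs on chromosome 17, 1 of 18 measured was lower and none higher, and none in either direction over the list alone, with a median log2 fold change of -0.12 (limma camera adjusted p = 0.265). Sex-linked genes differed within the CBS-KO group. Xist, the RNA that silences an X chromosome in females, had log2 values of 12.68, 12.61 and 12.66 in WT 1 to 3 and 12.23 in CBS-KO 3, against 6.02 and 6.18 in CBS-KO 1 and 2. The Y-linked Eif2s3y had values of 9.41 and 9.19 in CBS-KO 1 and 2 and of at most 4.90 elsewhere, so Y-linked signal was present in 0 of 3 WT and 2 of 3 CBS-KO arrays. Genotype and sex were therefore partly confounded in every comparison of the groups.

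**Figure D1:**
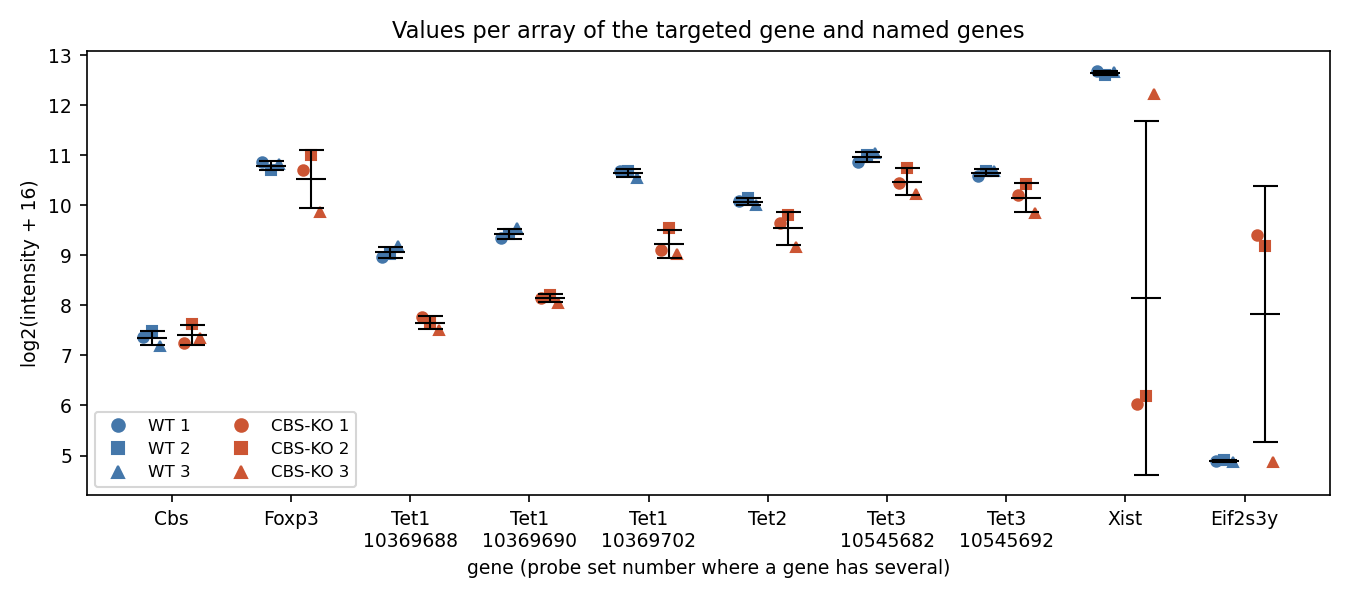
Values of the targeted gene, Foxp3, the Tet genes and 2 sex-linked genes on each array, on the log2(intensity + 16) scale, with the group mean and SD (n = 3 arrays per group). Cbs overlapped between groups, the 3 Tet1 probe sets lay lower on all 3 CBS-KO arrays than on any WT array, and Xist and Eif2s3y set CBS-KO 1 and 2 apart from CBS-KO 3.

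The 12 largest increases in CBS-KO cells included products of granulocytes and red cell precursors. Ngp, a granule protein of neutrophil precursors, rose from a log2 level of 7.29 in WT (log2 fold change 5.33, SE 0.38, n = 3 per group, limma adjusted p = 0.00263), and Lcn2, an iron-scavenging neutrophil protein, rose from 7.38 (5.33, SE 0.19, adjusted p = 0.000199). S100a8 and S100a9, the subunits of calprotectin, rose by 3.95 (SE 0.24) and 3.86 (SE 0.20). Slc4a1, the anion exchanger of the red cell membrane, rose by 4.31 (SE 0.38), and the Rh blood group genes Rhag and Rhd rose by 4.28 (SE 0.48) and 4.14 (SE 0.50). Completing the 12 largest increases were Tlcd4 (4.75), Gdpd3 (4.60), Klk1b22 (4.50), Cldn13 (4.47) and Wfdc17 (3.99). Of the 12 largest increases, 7 had a WT mean below the filter level of 6.987, and of the 12 largest decreases, 4 had a CBS-KO mean below it, where the background of the array is not known, so the size of these changes depends on that floor. In all, 1995 of 20856 tested probe sets passed an adjusted p of 0.05, 1062 higher in CBS-KO (855 named genes) and 933 lower (596 named genes). Of these, 715 were at least 2-fold higher and 222 at least 2-fold lower, and 56 against 6 reached 8-fold. At an unadjusted p under 0.05 there were 6443 probe sets, and 36.7% of tested probe sets had no overlap between the groups, where chance gives 10%. The count rested on single arrays: it was 93 without WT 1, 73 without WT 2, 672 without WT 3, 166 without CBS-KO 1, 6427 without CBS-KO 2 and 1377 without CBS-KO 3, and 4976 with sex as a model term. Among the 24 genes named for the size of their change, 17 passed under every limma setting that tested them. Tlcd4, Rhd, Wfdc17 and Xkrx lost their call without WT 1, WT 2 or CBS-KO 1, Cldn13 without WT 1 or WT 2, Rhag without WT 2 or CBS-KO 1, and Als2cl without WT 1, WT 2, WT 3 or CBS-KO 1. In a plain test without a shared variance, 4 of the 12 increases and 5 of the 12 decreases passed.

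Markers of neutrophils, monocytes and red cell precursors, cell types other than the CD4+ T cell, rose as groups. Of 14 neutrophil genes, 13 were higher (median log2 fold change 3.36), among them Ltf, the iron binder lactoferrin (3.82, SE 0.39), Mpo, the myeloperoxidase of azurophil granules (3.36, SE 0.51), and Mmp8, the neutrophil collagenase (3.35, SE 0.29). Adjusted over the list alone, all 14 passed, and the list's camera adjusted p of 1.77e-13 became an adjusted p = 0.6 with an estimated correlation. Of 15 monocyte and macrophage genes, 14 were higher, also when adjusted over the list alone (median 2.17). Lysozyme 2, Lyz2, rose by 3.67 (SE 0.39), the myeloid transcription factor Spi1 by 2.42 (SE 0.27) and the complement component C1qb by 2.37 (SE 0.30), and the camera adjusted p of 3.48e-10 became an adjusted p = 0.6 with an estimated correlation. All 5 measured erythroid genes of the 14 listed were higher, also over the list alone (median 3.002). They were Alas2, the erythroid haem synthesis enzyme (3.002, SE 0.18), Slc4a1, Car2, Epb42 and the transcription factor Klf1 (2.76, SE 0.45). Their camera adjusted p of 7.81e-06 became an adjusted p = 0.6 with an estimated correlation. In the single arrays the neutrophil list stood 3.59, 3.64 and 3.12 above the WT mean in CBS-KO 1 to 3, the monocyte list 1.77, 2.30 and 1.76, and the erythroid list 3.38, 2.59 and 3.70. Without WT 2, the array whose removal cost most, 6 neutrophil, 0 monocyte and 2 erythroid genes passed, and without WT 1 these counts were 6, 1 and 2. Without CBS-KO 1 they were 7, 5 and 2.

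NK cell and dendritic cell markers rose as well. Of 8 NK cell genes, 4 were higher (5 over the list alone, median 0.98): Fcer1g (2.22, SE 0.23) and Tyrobp (2.17, SE 0.28), signalling adaptors shared with myeloid cells, the activating receptor gene Ncr1 (2.06, SE 0.29), and the granzyme gene Gzma (1.38, SE 0.15). Of 9 dendritic cell genes, 4 were higher (7 over the list alone, median 1.04), with the growth factor receptor gene Flt3 at 2.19 (SE 0.24) and Clec9a, a receptor for dead cells, at 1.69 (SE 0.39). Both lists had a camera adjusted p of 0.000803 and an adjusted p = 0.6 with an estimated correlation, and in CBS-KO 3 alone against the WT arrays they did not pass (0.165 and 0.102), nor did the NK cell list with sex as a model term (0.0544), within ranges over all settings of 4.8e-06 to 0.6 and 1.29e-05 to 0.6. Without WT 1 or WT 2, 0 NK cell genes passed and 1 and 0 dendritic cell genes, and without CBS-KO 1, 1 of each. In fry the adjusted p was 0.0512 for the NK cell list and 0.0296 for the dendritic cell list. The plasma cell list also shifted up (median 0.88, camera adjusted p = 0.00355) but not in fry (adjusted p = 0.114). Only Tnfrsf17, a survival receptor gene of plasma cells, passed by itself (1.06, SE 0.24), with 5 of 6 genes over the list alone. The list's shift was not stable. It had an adjusted p = 0.6 with an estimated correlation and 0.202 with sex as a model term (range over all settings 4.26e-05 to 0.6), and 0 members passed without WT 1, WT 2, WT 3 or CBS-KO 1. No shift was called for B cell genes (median 0.10, camera adjusted p = 0.269), where only Ighm, the IgM heavy chain gene, was higher (1.53, SE 0.23, also over the list alone). The B cell mean was 0.10, 1.28 and -0.47 relative to WT in CBS-KO 1 to 3, and without CBS-KO 3 the list passed as higher (median 0.52, adjusted p = 0.00213, range over all settings 0.00213 to 0.871). Ighm lost its call without WT 1, WT 2, WT 3 or CBS-KO 1, when 0 B cell genes passed. Platelet genes (2 higher and 1 lower of 7, camera adjusted p = 0.264), CD8 T cell genes (0 of 6, 0.952), immature thymocyte genes (1 higher and 1 lower of 7, 0.609), and stromal and endothelial genes (0 of 9, 0.903) were not called. The platelet list passed as higher with no filter (median 0.37, adjusted p = 0.0488, range over all settings 0.0488 to 0.822). Its lower gene was Itgb3, which is also in the naive and quiescence list and is counted there again. Over the lists alone the platelet and thymocyte counts did not differ, the CD8 count stayed 0, and 1 stromal gene was lower. Median and mean had opposite signs for the thymocyte list (-0.11 and 0.10, test downward) and for the stromal list (0.08 and -0.10, test upward).

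**Figure D2:**
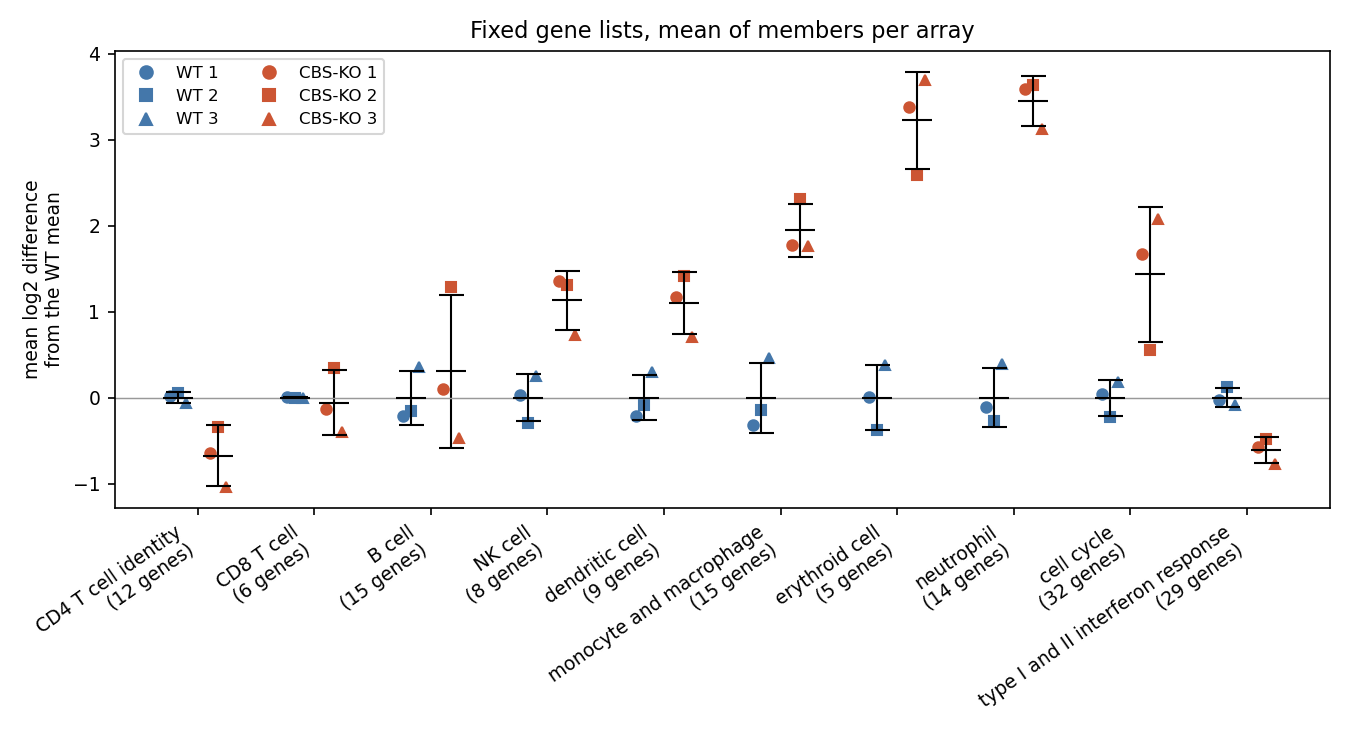
Mean log2 difference from the WT mean over the measured genes of 10 gene lists, for each array, with the mean and SD over the 3 arrays of a group. The neutrophil, monocyte and erythroid means of every CBS-KO array lay above all WT arrays, the CD4 T cell identity and interferon means lay below them, and the B cell means of the CBS-KO arrays ran from -0.47 to 1.28.

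Genes that define CD4+ T cells and their resting state fell. All 12 CD4 T cell identity genes had negative log2 fold changes (median -0.67), and 4 passed over all probe sets against 11 over the list alone. The T cell receptor chains Cd3d (-1.12, SE 0.18) and Cd3g (-0.74, SE 0.13), the co-stimulatory receptor Cd28 (-0.86, SE 0.21) and the adhesion receptor Cd2 (-0.80, SE 0.19) were lower. Cd28 and Cd2 lost their calls after quantile normalization, with no filter and under the other variance models. The list had a camera adjusted p of 1.07e-05 and an adjusted p = 0.6 with an estimated correlation. In 19 naive and quiescence genes all values were negative (median -0.64, camera adjusted p = 2.73e-07, adjusted p = 0.6 with an estimated correlation), and 4 passed over all probe sets against 16 over the list alone. These were the integrin gene Itgb3 (-1.29, SE 0.15), the chromatin organiser Satb1 (-1.07, SE 0.19), Slfn2 (-0.71, SE 0.16), which is needed for T cell quiescence, and the anti-proliferative gene Tob1 (-0.49, SE 0.12). T cell receptor signalling genes shifted down too (median -0.49, camera adjusted p = 1.6e-06, adjusted p = 0.646 with an estimated correlation), with 3 of 24 lower and 14 over the list alone, led by the Src-family kinase Fyn (-0.60, SE 0.13). Cd28 is in this list too and was counted again. In fry the CD4 identity, naive and T cell receptor lists did not pass (adjusted p = 0.0962, 0.0953 and 0.116). In the same arrays the CD4 identity mean was -0.65, -0.34 and -1.04 in CBS-KO 1 to 3, beside neutrophil list means of 3.59, 3.64 and 3.12 and erythroid list means of 3.38, 2.59 and 3.70. Without WT 1, WT 2 or CBS-KO 1, 0 members of these 3 lists passed, and without WT 3, 1 did, while without CBS-KO 2, 12, 19 and 16 did.

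Genes of the interferon response list fell as a group. Of 29 measured members of the type I and II interferon list, 12 were lower and 1 was higher over all probe sets, and 18 and 1 over the list alone (median -0.68). Oasl2, an antiviral oligoadenylate synthetase-like gene, fell most (-2.29, SE 0.19, limma adjusted p = 0.00417), followed by Ifi27l2a (-1.42, SE 0.19), the antiviral RNA-binding Ifit1 (-1.41, SE 0.14), Rtp4 (-1.28, SE 0.18) and Ifit3 (-1.07, SE 0.12). The exception among members that passed was Isg20, an interferon-induced exonuclease (1.02, SE 0.14), and 5 of the 29 had positive log2 fold changes. Of 14 genes named Ifi, some of them outside this list, 7 were lower and 4 higher, as given under the other observations. The list had a camera adjusted p of 2.73e-07, an adjusted p = 0.6 with an estimated correlation, and 0.0296 in limma's fry, which asks whether the genes move one way without comparing them with other genes. The list mean relative to WT was -0.58, -0.48 and -0.77 in CBS-KO 1 to 3, beside CD4 identity means of -0.65, -0.34 and -1.04. Without WT 1, 2 members passed as lower, without WT 2, 1, without WT 3, 8, without CBS-KO 1, 3 and without CBS-KO 2, 19. Oasl2 passed under every limma setting but not in the plain test without a shared variance.

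Among the enzymes that write and erase DNA methylation, Tet1 fell. Tet1 oxidises 5-methylcytosine, the step that starts demethylation, and demethylation of its regulatory regions keeps Foxp3, the lineage factor of regulatory T cells, expressed. The 3 Tet1 probe sets (10369688, 10369690 and 10369702) had log2 fold changes of -1.41 (SE 0.13, limma adjusted p = 0.00615), -1.29 (SE 0.12, 0.00628) and -1.42 (SE 0.16, 0.0103), and all CBS-KO arrays lay below all WT arrays. Tet2 had a log2 fold change of -0.53 (SE 0.18, adjusted p = 0.101) and the 2 Tet3 probe sets of -0.49 (SE 0.15, 0.0821) and -0.50 (SE 0.16, 0.094), none past the threshold. Without CBS-KO 2, Tet2 (-0.66, adjusted p = 0.0293) and the Tet3 probe sets (0.0114 and 0.018) passed, and over the limma settings the adjusted p ran from 0.000737 to 0.274 for Tet2, from 0.000258 to 0.238 and from 0.000428 to 0.256 for Tet3. These low ends came from array weights, whose fit did not converge, and without that fit they were 0.0108 for Tet2 and 0.0114 and 0.0107 for Tet3. Foxp3 differed by -0.27 (SE 0.28, adjusted p = 0.565), with a level of 10.79 ± 0.08 (SD) in WT and 10.53 ± 0.59 in CBS-KO cells. Its difference became 0.06 without CBS-KO 3 (adjusted p = 0.813), and with sex as a model term, when the estimate rests on CBS-KO 3, it was -0.92 (0.0178), with a range of 0.01 to 0.813 over the limma settings. Of 21 measured DNA methylation and demethylation genes, Tet1 was lower and Idh1, a cytosolic isocitrate dehydrogenase, was higher (0.81, SE 0.17), with 2 each way over the list alone, Dnmt3a (-0.62, SE 0.16) and Uhrf1 (1.69, SE 0.45) being the others. The list was not shifted (median 0.11, camera adjusted p = 0.493), and Idh1 lost its call without WT 1, WT 2, WT 3, CBS-KO 1 or CBS-KO 3, when 0 members were higher. The brightest Tet1 probe set lost its call without WT 1 (adjusted p = 0.0668), WT 2 (0.0694) or CBS-KO 1 (0.0567), against a range of 5.67e-06 to 0.0694 over the limma settings. Probe set 10369690 lost its call without WT 2 (0.0524, range 9.08e-06 to 0.0524), and 10369688 kept its call under every limma setting (1.18e-05 to 0.0484), where without array weights the low ends were 0.00164 for the brightest Tet1 probe set and 0.00241 and 0.00278 for these.

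**Figure D3:**
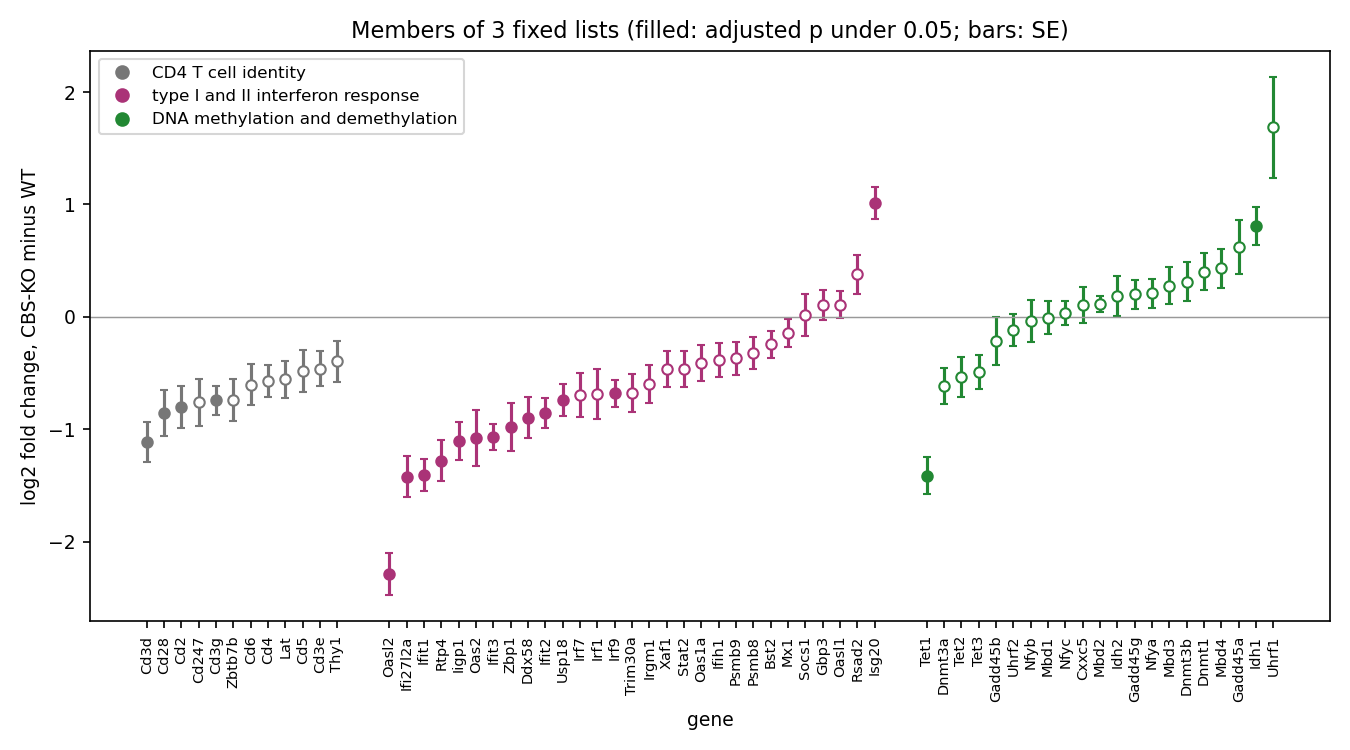
Log2 fold change (CBS-KO minus WT, 3 arrays per group) of each measured gene in the CD4 T cell identity, interferon response and DNA methylation lists, with the SE as bars and filled symbols for an adjusted p under 0.05. Tet1 at -1.42 lay below every CD4 T cell identity gene, the lowest of which was Cd3d at -1.12, and Oasl2 at -2.29 was the lowest value of the 3 lists.

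Of the lists of T helper subsets, the follicular helper list alone was called in the model without sex. Regulatory T cell genes had a median of -0.21 (camera adjusted p = 0.108), and of 27 only Lrrc32, the receptor that displays latent TGF-beta, was lower (-1.43, SE 0.24, also over the list alone). The list passed as lower without WT 2 (0.0376), CBS-KO 1 (0.0301) or CBS-KO 2 (0.0162) and with sex as a model term (median -0.55, 1.96e-05), with a range of 1.96e-05 to 0.822 over all settings. With that term the Th1 list (median -0.50, adjusted p = 0.0159, range 0.0159 to 0.969) and the Th2 list (median -0.31, 0.0318, range 0.0318 to 0.822) passed as lower too, as they did in the female arrays alone, and in both fits the estimate rests on CBS-KO 3. Lrrc32 lost its call without WT 1 (0.108), WT 2 (0.0824), WT 3 (0.0699) or CBS-KO 1 (0.096), with a range of 2.61e-05 to 0.108 (from 0.0038 without array weights). In the Th1 list (median -0.09, camera adjusted p = 0.71) the chemokine gene Ccl3 was higher (1.88, SE 0.33) and the transcription factor gene Eomes lower (-0.71, SE 0.14), also over the list alone. In the Th2 list (median -0.30, 0.309) Pparg, a nuclear receptor also expressed by macrophages, was higher (0.81, SE 0.17), against 2 higher and 2 lower of 12 over the list alone. In the Th17 list (median 0.19, 0.493) Tmem176b (1.51, SE 0.23) and Tmem176a (1.37, SE 0.23) were higher and Batf, a transcription factor of T cell differentiation, lower (-0.59, SE 0.12), against 3 higher and 1 lower of 12 over the list alone. The follicular helper list shifted down (median -0.63, camera adjusted p = 0.00617, adjusted p = 0.796 with an estimated correlation), with Sh2d1a, an adaptor of T cell and B cell contact (-1.02, SE 0.15), and Cd200 (-0.88, SE 0.20) lower among 15 genes and 8 lower over the list alone. Its means were -0.38, -0.09 and -0.84 in CBS-KO 1 to 3, beside CD4 identity means of -0.65, -0.34 and -1.04 and erythroid means of 3.38, 2.59 and 3.70. This shift was lost without CBS-KO 3 (adjusted p = 0.054) and in fry (adjusted p = 0.198), with a range over all settings of 3.41e-06 to 0.796. Without WT 1, WT 2 or CBS-KO 1, 0 members of these 5 lists passed, and without WT 3 only Tmem176b, Tmem176a and 1 follicular helper gene did. Il2 and Ifng, cytokines of activated T cells, differed by -0.23 (SE 0.14, adjusted p = 0.311) and -0.50 (SE 0.23, 0.199), and Il17a and Il10 lay below the level needed for testing.

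Signalling lists gave a mixed picture. TGF-beta signalling shifted down at the edge of the threshold (median -0.35, camera adjusted p = 0.0477, adjusted p = 0.822 with an estimated correlation). In fry it did not pass (adjusted p = 0.287). The inhibitor Smad7 (-0.86, SE 0.19), the co-receptor Tgfbr3 (-0.69, SE 0.11), Itgb8 (-0.79, SE 0.16), which activates latent TGF-beta, and Skil (-0.66, SE 0.16) were lower among 22 genes, and Tgfbi, an induced matrix protein also made by macrophages, was 8.06-fold higher (3.01, SE 0.31). Over the list alone 8 were lower and 2 higher. The list means were -0.17, 0.07 and -0.34 in CBS-KO 1 to 3 and the list medians -0.38, -0.10 and -0.61. Beside them stood CD4 identity means of -0.65, -0.34 and -1.04 and erythroid means of 3.38, 2.59 and 3.70. The shift was lost without WT 2 (0.0527), WT 3 (0.0916) or CBS-KO 3 (0.175), and after quantile normalisation its adjusted p was 0.05 (range over all settings 0.00107 to 0.822). Without WT 2, 0 of its genes passed, and without WT 1, WT 3 or CBS-KO 1, 1 gene passed, as higher. Activation and memory genes were called in both directions (4 higher and 3 lower of 34, 10 and 7 over the list alone, median 0.05, camera adjusted p = 0.846). None of 18 IL-2 and STAT5 genes passed in either adjustment (median -0.19, 0.269). For the p53 and apoptosis list (median -0.26, 0.0553), 4 of 20 were lower, with the death receptor gene Fas at -0.87 (SE 0.15), and 2 were higher, with 9 and 3 over the list alone, and the list passed with the arrays at a common median (0.0273), with sex as a model term (0.023) and without WT 1 (0.0499) or CBS-KO 2 (0.0406), with a range of 0.023 to 0.6 over all settings. Without WT 1, WT 2, WT 3 or CBS-KO 1, 0 p53 genes passed, and 0, 1, 4 and 1 activation genes did. The IL-2 and STAT5 list passed as lower without CBS-KO 2 (0.0439) and with sex as a model term (0.0159, range 0.0159 to 0.822).

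Genes of proliferation rose together. All 32 cell cycle genes had positive log2 fold changes (median 1.47), and 12 passed over all probe sets against 31 over the list alone. Mki67, the proliferation antigen Ki-67, was 3.22-fold higher (1.69, SE 0.29, limma adjusted p = 0.0241), the cyclin gene Ccna2 rose by 1.99 (SE 0.36), and the nucleotide synthesis genes Tk1 and Rrm2 rose by 1.65 (SE 0.30) and 1.96 (SE 0.37). The camera adjusted p was 1.51e-11, with an adjusted p = 0.6 with an estimated correlation. In fry the list did not pass (adjusted p = 0.099). The list mean stood 1.68, 0.56 and 2.07 above WT in CBS-KO 1 to 3, beside erythroid means of 3.38, 2.59 and 3.70. No member passed without any of WT 1, WT 2, WT 3 or CBS-KO 1, 4 passed without CBS-KO 3, and all 32 passed without CBS-KO 2.

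Sulfur, folate and redox genes shifted upward. In the hydrogen sulfide and transsulfuration list (median 0.42, camera adjusted p = 0.00683, adjusted p = 0.651 with an estimated correlation), 3 of 16 genes were higher and 6 over the list alone. The members that passed were Gclc (0.88, SE 0.17) and Gclm (1.48, SE 0.29), the subunits of the enzyme that starts glutathione synthesis, and the methanethiol oxidase gene Selenbp1 (1.62, SE 0.36). Gclc and Gclm are also in the antioxidant and NRF2 list and were counted there again, so these lists are not independent. Mpst, an enzyme that also makes hydrogen sulfide, differed by 0.41 (SE 0.24, adjusted p = 0.307), and Cth, which acts after CBS in transsulfuration, lay below the level needed for testing. Of 16 methionine and folate cycle genes, 4 were higher: the spermidine synthase gene Srm (1.01, SE 0.19), the mitochondrial serine hydroxymethyltransferase gene Shmt2 (0.93, SE 0.18), Tyms (1.59, SE 0.34) and Mthfd1 (1.54, SE 0.34). Over the list alone 5 were higher and 1 lower, and Tyms is also in the cell cycle list. The list (median 0.23, camera adjusted p = 0.0451, adjusted p = 0.822 with an estimated correlation) lost its call without WT 2 (0.0529) or CBS-KO 3 (0.175) and with the arrays at a common median (0.0565), with a range of 0.00173 to 0.822 over all settings. In CBS-KO 1 to 3 the means were 0.47, 0.19 and 0.73 for the hydrogen sulfide list and 0.45, 0.10 and 0.73 for the methionine list, beside erythroid means of 3.38, 2.59 and 3.70. Antioxidant and NRF2 genes rose (9 of 24, 15 over the list alone, median 0.58, camera adjusted p = 5.05e-07, adjusted p = 0.6 with an estimated correlation), among them glutathione reductase, Gsr (1.51, SE 0.14), glutathione peroxidase, Gpx1 (1.02, SE 0.12), and the haem-degrading Hmox1 (2.21, SE 0.29). Mean levels of this list were 0.81, 0.38 and 1.08 above WT in CBS-KO 1 to 3, beside erythroid means of 3.38, 2.59 and 3.70. The cell cycle means of 1.68, 0.56 and 2.07 ran in the same order, and with 3 arrays a shared order does not point to a cell source. In fry the hydrogen sulfide, methionine and antioxidant lists did not pass (adjusted p = 0.126, 0.33 and 0.0848). Without WT 1, WT 2, WT 3 or CBS-KO 1, 1, 1, 3 and 2 antioxidant genes passed and none of the other 2 lists, and without CBS-KO 2 18 antioxidant genes passed.

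Lists of stress and energy genes were tested next. Asns, the asparagine synthetase induced by amino acid shortage, was 11.4-fold higher (3.52, SE 0.45, limma adjusted p = 0.0131), and the endoplasmic reticulum genes Sdf2l1 (1.20, SE 0.17) and Creld2 (0.70, SE 0.11) and the amino acid transporter subunit gene Slc3a2 (0.52, SE 0.08) rose with it. These were the 4 higher genes of 29 in the unfolded protein and amino acid stress list (7 over the list alone, median 0.29, camera adjusted p = 0.000924). The list had an adjusted p = 0.6 with an estimated correlation, 0.0296 in fry and 0.0766 with sex as a model term, where the median was 0.26, within a range of 1.47e-05 to 0.6. Its means were 0.37, 0.42 and 0.35 in CBS-KO 1 to 3, beside plasma cell means of 0.92, 1.51 and 0.42, and 0 members passed without WT 1, WT 2 or CBS-KO 1. Xbp1 is in both the plasma cell and the unfolded protein list, so these means are not independent. Asns lost its call without WT 1 (0.0567), WT 2 (0.0505) or CBS-KO 1 (0.0654), with a range of 3.07e-05 to 0.0654 (from 0.00259 without array weights). Of 35 oxidative phosphorylation genes, 2 were higher in either adjustment (median 0.21, camera adjusted p = 0.0018, adjusted p = 0.822 with an estimated correlation): Atp5g1 of ATP synthase (1.04, SE 0.15) and Uqcrc1 of complex III (0.61, SE 0.12). The list means were 0.31, -0.09 and 0.56 in CBS-KO 1 to 3, beside erythroid means of 3.38, 2.59 and 3.70. That shift was lost in fry (adjusted p = 0.419) and without CBS-KO 3 (median 0.08, adjusted p = 0.0857, range 3.07e-07 to 0.822). Of its members, 0 passed without WT 1, WT 2, WT 3 or CBS-KO 1. Glycolysis genes were called in both directions (2 higher and 2 lower of 19, 3 and 3 over the list alone, camera adjusted p = 0.903), with Pdk1, a kinase that restrains pyruvate oxidation, at -1.26 (SE 0.16), and the list's median and mean of 0.01 and 0.04 stood against a downward test. Among glucocorticoid response genes (3 higher and 2 lower of 18, 5 and 3 over the list alone, median 0.12, 0.585), the metallothioneins Mt1 (2.56, SE 0.37) and Mt2 (2.34, SE 0.29) rose. Mt1 lost its call without WT 1, WT 2 or CBS-KO 1 and Mt2 without CBS-KO 1. Without WT 1, WT 2 or CBS-KO 1, 0 glycolysis genes and 1, 1 and 0 glucocorticoid genes passed. In the immediate early and heat shock list (median 0.08, 0.493) only Ier3 passed in either adjustment (0.71, SE 0.10), among 23 genes, and Ier3 lost its call without WT 1, WT 2 or CBS-KO 1. Ribosomal protein genes were not called (0 of 24 in either adjustment, median -0.11, 0.0663) but passed as lower after quantile normalisation (0.0259) and without WT 1 (0.0137) or CBS-KO 3 (0.00821), with a range of 0.00821 to 0.822. Of the 36 lists tested, 12 were called higher and 6 lower, 0 held with an estimated correlation, where the smallest adjusted p was 0.6, and 6 held in fry, namely the neutrophil, monocyte, erythroid, dendritic, unfolded protein and interferon lists.

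The 12 largest decreases included several genes of chromosome 7. A probe set of Rps13, a ribosomal protein gene, read -5.98 (SE 0.29), but the other 2 Rps13 probe sets read -0.19 (SE 0.13) and -0.14 (SE 0.09) without passing, so no fall of the gene can be read from it. Trim12a, of the TRIM family, which includes antiviral ubiquitin ligases, fell by 5.27 on the log2 scale (SE 0.17, limma adjusted p = 0.000199). Its level was 11.66 ± 0.22 (SD) in WT and 6.39 ± 0.21 in CBS-KO cells. Trim30d, of the same family, fell by 3.40 (SE 0.20), and the genes Gm1966, BC147527 and Gm4759 had log2 fold changes of -3.45 (SE 0.25), -3.20 (SE 0.12) and -1.98 (SE 0.17), all past the test. Trim12a, Trim30d, Gm4759 and Gm1966 lay within 19 neighbouring tested genes of chromosome 7 in the gene order of GRCm38.p6, and these 4 were the members of that stretch that passed. Their close relatives Trim12c (-0.47, SE 0.13, adjusted p = 0.0706) and Trim30a (-0.68, SE 0.17, 0.0529), between them in that order, did not pass, and probes of such paralogs can share targets. The remaining genes among the 12 largest decreases were Oasl2, the interferon-induced Ifi214 (-2.22, SE 0.21), Lypd6b (-2.17, SE 0.14), Als2cl (-1.93, SE 0.29), Arhgap29, a GTPase-activating protein gene (-1.89, SE 0.19), and Xkrx (-1.88, SE 0.21).

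**Figure D4:**
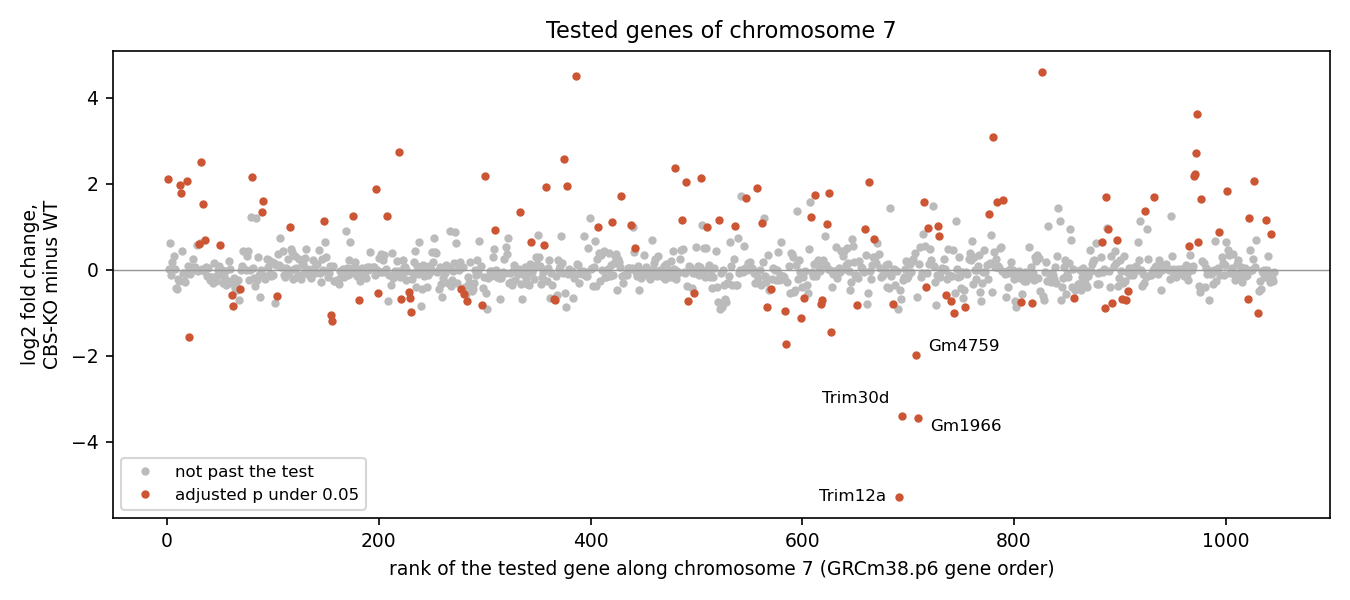
Log2 fold change (CBS-KO minus WT, 3 arrays per group) of the 1046 tested genes of chromosome 7 by their rank along it, with coloured points for an adjusted p under 0.05. Trim12a (-5.27), Gm1966 (-3.45), Trim30d (-3.40) and Gm4759 (-1.98) lie close together at ranks 691 to 709.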

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

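Except for the count over all splits of the arrays, every test in this section was chosen after the result it concerns was seen. Where a test could not decide, it was read as open, also against the prediction written for it.

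Of 13904 probe sets below the filter, 40 had a highest CBS-KO value more than 2 log2 units above the highest WT value, and they stood out because the filter on the mean of all arrays had removed genes with high values in CBS-KO arrays. Removed probe sets with high values in WT arrays were not searched for, so this does not show a loss in 1 direction. The 40 included 11 named genes. The Y-linked Eif2s3y (4.51), Uty (4.30), Kdm5d (2.99) and Srsy (2.90) were high in CBS-KO 1 and 2 alone. The X-linked Bex4 (3.91) and Hmgb3 (3.27), with Tspan8 (2.50) and the epoxide hydrolase gene Ephx2 (2.05), were highest in CBS-KO 3. Il1f9 (2.50), the RNA sensor gene Tlr8 (2.11) and Mirt2 (2.06) were highest in CBS-KO 2. These 7 lay above every WT array in all 3 CBS-KO arrays. No biological explanation was tested for these genes.

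The split into WT and CBS-KO called 1995 probe sets and the other splits called 0, so 1 of 10 splits called as many, which is too few splits to tell a grouping by chance apart.

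The neutrophil, monocyte and erythroid markers rose in cells labelled CD4+ T cells. A lower share of T cells with the other cells in their WT proportions would raise the markers of the other cells alike. For the neutrophil list the values argue against it, because its median exceeded the B cell list median by at least 2.774 log2 units in every CBS-KO array. This rests on the B cell list as the only comparator, whose CBS-KO means ran from -0.47 to 1.28, and on its signal coming from B cells. That the B cell list was not called was known when the test was chosen, so the gap partly restates the list shifts. Its size also depends on the floor, since 2 of the 34 markers had a WT mean above the median of tested genes. The sex of the animals stays open: the female CBS-KO array lay at least 1.302 above the highest WT array in all 3 lists, but this is 1 array. More RNA of these cells in the CBS-KO samples stays open too, since the 94.1% of the 34 markers that passed as higher restate the rise; 1 of the 34, Tyrobp, is in another list. Whether such cells were carried over during isolation or were more frequent in the animals cannot be told, since any sort or gate is not known here.

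Tet1 and the interferon genes fell in the same arrays, and dilution of T cell RNA by other cells was weighed. Tet1 minus the CD4 identity gene that fell most was -0.293, -0.445 and -0.029 in CBS-KO 1 to 3, so dilution may account for part of it and the test leaves this open. Relative to WT the mean of the Tet1 probe sets was -1.367, -1.231 and -1.515, beside identity medians of -0.661, -0.347 and -0.965. The interferon genes below are set against that median, so the Tet1 and interferon differences are not on the same scale. The sex of the animals stays open for Tet1, since the gap of at least 1.285 below the lowest WT array comes from 1 female CBS-KO array. For interferon genes the list median minus the identity median reached 0.184 in CBS-KO 3, which leaves dilution open. For the members that passed the difference was -0.381, -0.553 and -0.316 in CBS-KO 1 to 3, which also leaves it open, although the prediction written for this test spoke of these members.

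Trim12a, Trim30d and Gm1966 were among the largest decreases and lay near each other on chromosome 7. A general fall of interferon genes stays open: their median minus the list member that fell most was -1.163, but the 3 genes were picked for the size of their fall. The values argue against dilution of T cell RNA alone, because their median minus the identity gene that fell most was -2.335. The largest SE of the 3 genes was 0.25, and the identity genes fell by between -0.40 and -1.12. The selection of the 3 genes for their fall applies here too. A segment of chromosome 7 that differs between the WT and CBS-KO animals is a candidate explanation: 4 of the 19 genes lower by over 1.5 lay within 40 neighbouring tested genes (permutation p = 4e-04, where 1e-04 is the smallest 10000 placements can give), against a largest run of 2 in the median and 4 at most under random placement, with the run length and the threshold set after the falls were seen. None of the 19 lay on chromosome 17 with Cbs, and related genes in the segment can share probes, which the placement does not allow for.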

How the results depend on the processing

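The count of changed probe sets depended on the setting, and the cause was not tested. It was 1126 with no filter (602 higher, 524 lower), 74 with a plain test per probe set without a shared variance (29 and 45), 4976 with a sex term (2309 and 2667), 6708 with the female arrays only (3476 and 3232), where 1 array is assumed to vary like the others, and 13534 with array weights (5751 and 7783), whose fit did not converge. Leaving out 1 array gave 73 (54 and 19, without WT replicate 2) to 6427 (3396 and 3031, without CBS-KO replicate 2), and all 1995 calls kept their sign. With the replicate block the count was 2093, 1503 of them shared. Residuals of arrays with the same number had r of 0.063, 0.158 and 0.108. Those of arrays with different numbers had r of -0.122 to 0.048, below every same-number value. Not all same-number values were over 0.1, the limit used, and residuals within a group are not independent, so pairing stays open. Lists called numbered 0 with an estimated correlation (0 higher, 0 lower) and 6 with fry (5 and 1). With the sex term 11 were lower, and the plasma cell, NK cell and unfolded protein lists were no longer called as higher. Cbs was at -0.13 with array weights, -0.048 without CBS-KO replicate 2 and 0.15 without CBS-KO replicate 1. No call was reversed. A fit without cross-hybridizing probe sets was not run, since no probe set name on this array ends in _x_at or _s_at.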

Other observations

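Genes named Zfp, many of them zinc finger genes, were lower more often than other genes, but not with every array left out. Of 280 tested genes named Zfp, 42 were lower and 1 higher, 15% lower against 4.2% of other genes (Fisher's exact test, adjusted p = 1.1e-09 over 320 tests), and 51 were lower after quantile normalization and 33 at a common median. Without WT 1, WT 2, WT 3, CBS-KO 1, CBS-KO 2 and CBS-KO 3 in turn, 0, 0, 10, 2, 85 and 15 were lower, and the share passed without WT 3 or CBS-KO 2 only (adjusted p from 1.21e-09 to 1). Zfp287 (-1.29, SE 0.17) and Zfp40 (-0.87, SE 0.12) were among them, and Zfp385a was the higher one (1.69, SE 0.19). C-type lectin genes were higher more often than other genes, 7 of 15 Clec genes under each of the 3 scalings (adjusted p = 0.00175), with the myeloid receptors Clec4a1 (2.50), Clec4a3 (2.51) and Clec7a (1.90). Without WT 1 or WT 2, 2 were higher. The share did not pass without WT 1 (adjusted p = 0.114), WT 2 (0.0946) or CBS-KO 2 (0.183), although 7 were higher without CBS-KO 2. Of 14 Aldh genes, 5 were higher (4 under both other scalings, 0 without WT 1, WT 2 or CBS-KO 1, adjusted p = 0.0486), led by Aldh1a1, a retinaldehyde dehydrogenase (3.42, SE 0.41). The Aldh share also did not pass without WT 3 (adjusted p = 0.252) or CBS-KO 3 (0.431). Of 11 Galnt genes, which start O-glycosylation, 4 were lower (5 after quantile normalization, 4 at a common median, 0 without WT 1, WT 2, WT 3 or CBS-KO 1, adjusted p = 0.0356), with Galnt10 at -0.95. In the same CBS-KO arrays, 1 to 3, the CD4 identity mean was -0.65, -0.34 and -1.04 relative to WT, the neutrophil mean 3.59, 3.64 and 3.12 and the erythroid mean 3.38, 2.59 and 3.70, and whether the families followed these was not tested. The 160 families were formed from gene names after the data were seen, and genes of a family are not independent. Of the 320 tests 10 passed, those besides these 4 and Ifi being the share of higher genes, lower than elsewhere for Zfp (adjusted p = 2.34e-05) and above it for names in H (13 of 54, 0.00239), Cd (15 of 78, 0.00832), Slc (30 of 231, 0.0176) and C (8 of 29, 0.0176), and 0 H, Cd and C genes were higher without WT 1 or WT 2 and 1 Slc gene. With 1 array left out the Slc share never passed, and the C share passed only without CBS-KO 1 (adjusted p = 0.0135). The shares for H and for higher Zfp genes passed only without CBS-KO 2 or CBS-KO 3. That for Cd passed only without WT 3 or CBS-KO 3.

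Ifi genes were lower more often than other genes: 7 of 14 were lower under all 3 scalings (adjusted p = 9.33e-05), and 4 were higher, a share that did not pass (adjusted p = 0.199). The lower share was lost without WT 2, when 1 was lower (adjusted p = 0.697, range with 1 array left out 3.86e-05 to 0.697), and the higher share passed without WT 3 (0.0345) or CBS-KO 1 (0.0178, range 0.0178 to 0.826). Ifi206 (-1.73) and Ifi213 (-1.49) fell with Ifi214, while Ifi205 (3.03), Ifi207 (2.54) and Ifi44l (2.23) rose. The source of the Ifi genes that rose was not tested.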
